A study of Mus musculus with 3 samples.

How the data were processed

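Total RNA of adult mouse liver, fetal mouse liver and mouse bone marrow, all of the C57BL/6 strain, was measured on 3 Agilent whole-genome mouse expression arrays, 1 per tissue. Per the labels' protocols, the adult liver came from mice of 12 weeks and the fetal liver from gestation day 13.5, RNA was extracted with a tissue kit, and amplified cRNA was labelled with Cy3 in a 1-colour design. The wording leaves open whether the age of 12 weeks also holds for the bone marrow donors. Sex and the number of animals per sample are not given in the sources used here. Each tissue was its own group and no sample was left out. The file headers place the 3 arrays on 1 slide read in 1 scan, so no slide or scan separates them.

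Per the file headers and the submitters' processing notes, spots were read with Agilent Feature Extraction 10.5.1.1. The processed signal intensity of a spot, as deposited in the scanner files, was background-subtracted and spatially detrended on the linear scale, dim spots carried a surrogate value, and nothing was normalized between arrays, per the file headers. The mean spot intensity, the local background intensity and the error of the processed signal stand beside it, also on the linear scale. The authors also deposited a table of the whole series with 3 columns per array, named raw, normalized and fold change. Set against the scanner files, the raw intensity column of that deposited table equalled the error of the processed signal within 1% on 45018 of 45018 spots of each array. It equalled the processed signal itself within 1% on only 15081 spots of the adult liver array, 12064 of fetal liver and 13199 of bone marrow. The authors' normalized ratio column was this error divided by its 75th percentile on the array, which was 29.3 for adult liver, 37.8 for fetal liver and 85.3 for bone marrow. Its medians were 0.187, 0.130 and 0.0936, on a linear scale without centring. The deposited fold column was the ratio of the normalized value to that of adult liver, with medians of 1.00, 0.619 and 0.430. Since it holds errors in place of signals, the table was used only as an alternative, and the signals reported here come from the scanner files.

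From the scanner files, log2 of the processed signal minus the 75th percentile of its log2 values over all gene spots of the array was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Control spots and spots with an outlier flag were left out, the latter being 75 gene spots on the array of adult liver, 71 on that of fetal liver and 80 on that of bone marrow. Spots of 1 probe were averaged on the log2 scale. Of 41174 probes, 24844 were named through the accession in the file and a RefSeq table of mouse genes, 6045 through a current symbol, 1796 through an older symbol that points to 1 gene, and 60 kept the name in the file, a step added after Eraf was found without a current name. The remaining 8429 probes are not named here, and 3617 of them were well above background on at least 1 array. A spreadsheet had turned 49 probe names into dates, and 35 of these were restored through the accession. The named probes covered 19764 genes, 8606 of them with more than 1 probe. A gene was represented by the probe that was well above background on most arrays, with ties going to the brightest. Among genes with several probes that differed at least 4-fold, every probe did so in the same direction for 639 of 1729 between fetal and adult liver, 359 of 1101 between fetal liver and bone marrow, and 810 of 2200 between adult liver and bone marrow. A probe at least 4-fold the other way existed for 5, 6 and 28 of them. Coordinates are those of the array file, on mouse build mm9.

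With 1 array per tissue there is no spread between animals or samples, so no test, p-value, SD or SE across arrays is given, and all comparisons describe these 3 RNA samples. A gene was counted as different when 2 tissues differed at least 4-fold. Where its probe was not well above background in 1 of the 2 tissues, the fold is a lower bound, written "at least". It is computed against the higher of the probe's own signal and the lowest scaled signal among probes well above background on that array. That lowest signal is not the detection limit of each probe, and dim signals carry spot noise, so the bound is approximate. Where the probe was dim in both tissues, no fold was formed. No spot was saturated. A gene could take any of 6 patterns, at least 4-fold above or at least 4-fold below both other tissues. Pearson and Spearman correlations were taken across genes well above background on all 3 arrays, and genes are not independent replicates. Where the fetal liver level lay relative to the other tissues, between or outside them, was described only after the data were seen.

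Before the data were examined, 40 gene lists with 665 different genes were set for liver functions, blood cell lineages, other cell types of these organs, and tissues that could be carried along in dissection. Of their members, 11 had no named probe. For each list, the median difference was taken over members with a measured difference or a bound, with bounds at their bound. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these arrays only. Below, a list is said to stand apart when that percentile was under 2.5 or above 97.5. Genes named in the text follow a rule set at the same time. Per comparison it takes the 8 largest measured differences and the 4 brightest bounds in each direction. Per list it takes up to 4 members with the largest difference in the direction of the median and up to 3 members at least 4-fold the other way, and per pattern the 8 genes with the largest smallest difference. Alb, Afp, the adult beta globin gene, Hbb-bh1, Ptprc, Cd34, Kit and sex chromosome genes are always given. Some genes that the rule selects are not reported here. Genes outside this rule, of lipid storage, adipocytes and sex-biased liver expression, were singled out after their values were seen. Members of near-identical families (Mup, Hba, Hbb, Ear, Cyp2c, Cyp4a, Serpina1 and immunoglobulin genes) may share signal with their relatives on these probes.

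The only gene probes replicated on the arrays were 245 probes printed 10 times each. Among those well above background, the median SD of log2 signal between spots was 0.0703 in adult liver, 0.0663 in fetal liver and 0.0529 in bone marrow, which covers spot error only. The number of arrays limits the precision of every comparison. The code was tested on simulated arrays of 19764 genes. Each was a copy of the fetal liver array with a constant shift and random spot noise. The noise had an SD of 0.133 on the log2 scale, the largest root mean square among the 3 arrays for probes well above background. For probes not well above background it was 0.329 in adult liver, 0.406 in fetal liver and 0.350 in bone marrow. Changed genes were drawn only from bright genes with 1 probe. For fetal liver against adult liver and for fetal liver against bone marrow alike, 50 of 50 genes changed 5.66-fold, 50 of 50 changed 16.0-fold and 50 of 50 changed 256-fold were called in the right direction. None of the 50 genes changed 2.83-fold passed the 4-fold rule, and 0 unchanged genes did. Since dim probes were given the noise of bright ones, the simulation does not show how often dim genes are called wrongly.

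As alternatives set beforehand, the arrays were scaled by their median, by quantile normalization and by the 75th percentile of probes well above background on all 3 arrays. The background was corrected with normexp (limma 3.58.1 in R 4.3.3, offset 50) on the mean spot and local background intensity, and the authors' table was used in place of the scanner signals. Genes were also restricted to those well above background on all 3 arrays, taken without any filter or bound, represented by the mean of all probes, or left out where saturated, and the threshold was set to 2-fold and 8-fold. The limit of 0.05 within which a correlation counts as unchanged was chosen after the data were available. Scaling by the 7 E1A spike-in probes well above background on all 3 arrays was added after the data were seen. Figures were drawn with matplotlib 3.10.9.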

Results

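The series compares gene expression in the adult liver, the fetal liver and the bone marrow of C57BL/6 mice. At gestation day 13.5 the fetal liver is a main site of blood formation, the bone marrow takes that role after birth, and the adult liver serves metabolism and plasma protein synthesis. Each tissue was measured once on a 1-colour array of 45018 spots, 43379 of them for genes, so that no comparison has replicates. Gene spots well above background made up 52.6% of the adult liver array, 58.7% of the fetal liver array and 58.8% of the bone marrow array. The 75th percentile of the gene signals, to which every array was scaled, lay at 296.5, 386.0 and 894.5. The 100 brightest probes held 24.02%, 26.9% and 19.8% of the signal. Of 19764 genes, 12905 were well above background in adult liver, 13888 in fetal liver and 13961 in bone marrow, and 11701 in all 3 tissues.

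Fetal liver resembled bone marrow more than adult liver. Across the 11701 genes well above background everywhere, Pearson's r was 0.831 (Spearman's rho 0.830) between fetal liver and bone marrow, 0.727 (0.732) between fetal and adult liver, and 0.612 (0.626) between adult liver and bone marrow. Differences of at least 4-fold were found for 2593 of 14704 genes compared between fetal liver and bone marrow (17.6%), 3726 of 14207 between fetal and adult liver (26.2%), and 4826 of 14272 between adult liver and bone marrow (33.8%). Of the 1797 genes well above background everywhere that were at least 4-fold higher in adult liver than in bone marrow, 1176 had a fetal liver level nearer to bone marrow on the log2 scale. Of the 1423 such genes higher in bone marrow, 885 had one nearer to bone marrow. This description was added after the data were seen. Scaling to spike-ins, also added then, leaves the correlations unchanged but reverses the order of the counts, with 308 and 7983 genes between fetal liver and bone marrow against 2636 and 1477 between fetal and adult liver.

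**Figure D1:**
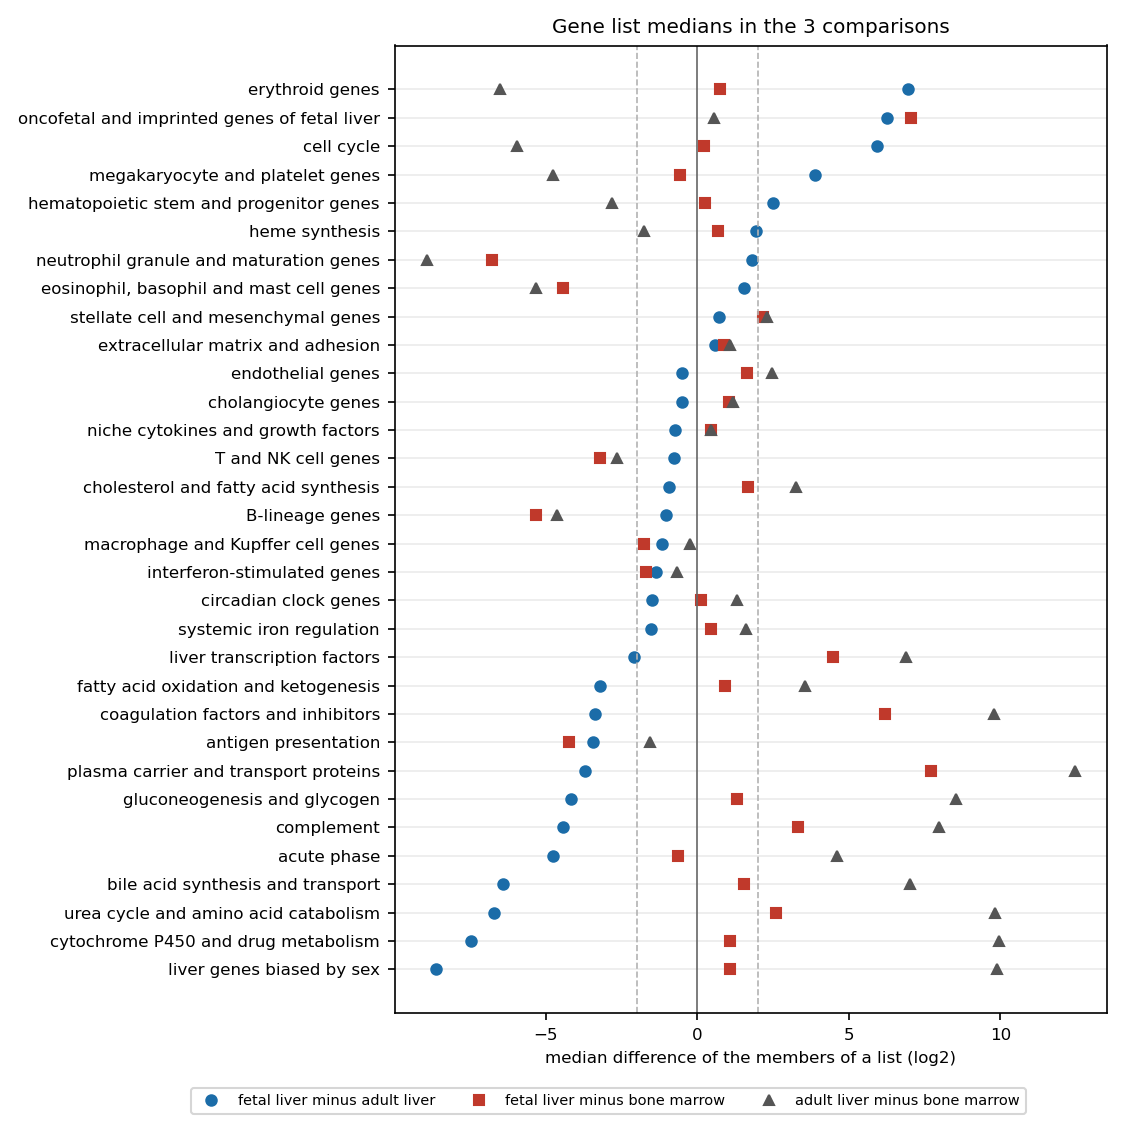
Median difference (log2) of the members of 32 gene lists with at least 9 members compared in every pair of tissues. Circles give fetal liver minus adult liver, squares fetal liver minus bone marrow and triangles adult liver minus bone marrow, and dashed lines mark 4-fold. Erythroid and cell cycle lists lie far to the right for fetal against adult liver and within 4-fold for fetal liver against bone marrow.

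Fetal and adult liver were compared to see what sets the blood-forming liver apart from the mature organ. Red cell genes, cell division genes and fetal growth genes were higher in fetal liver, and nearly every metabolic list was higher in adult liver. The largest measured differences towards fetal liver were those of the growth factor Igf2 (1850-fold), the fetal plasma protein Afp (1624-fold), the red cell anion exchanger Slc4a1 (1519-fold), the proliferation marker Mki67 (621-fold), Cd24a (445-fold), the embryonic globin Hbb-y (424-fold), Uhrf1 (416-fold) and the serine synthesis enzyme Phgdh (365-fold). The Afp probe (chromosome 5, 90937781 to 90937840, mm9) gave a signal of 210500 in fetal liver and 99.1 in adult liver. The Igf2 probe (chromosome 7, 149836673 to 149836709) gave 56220 and 23.2. The lowest signal well above background on the adult liver array was 18.9. Where the dim side lies this close to it, the size and rank of a fold are uncertain. Among genes not well above background in adult liver, Eraf, which encodes the alpha globin chaperone, was at least 3076-fold higher in fetal liver, Hemgn at least 1400-fold, Kel at least 1287-fold and Rhd at least 1190-fold. In total 1707 genes were higher in fetal liver, 1204 of them measured in both tissues.

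Of 25 erythroid genes, 24 were at least 4-fold higher in fetal than in adult liver, with a median of 125-fold. All 3 embryonic globins were higher, Hbb-bh1 by at least 834-fold and Hba-x by at least 188-fold. The adult beta globin gene (Hbb-b1 in the array file, Hbb-bt in the reference table) was 7.78-fold higher, with a signal near the top of the range in fetal liver. In heme synthesis, 6 of 12 genes were higher, among them the mitochondrial iron importer Slc25a37 (35.4-fold) and Abcb10 (8.21-fold), whereas Alas1, the housekeeping form of the first enzyme, was 7.12-fold lower. Of 28 cell cycle genes, 27 were higher with a median of 61.1-fold, led after Mki67 by Ccna2 (257-fold), Plk1 (223-fold) and Tpx2 (at least 184-fold). Of 18 oncofetal and imprinted genes compared, 17 were higher with a median of 75.7-fold, including Dlk1 (at least 355-fold) and H19 (299.8-fold). The platelet lineage was represented by 13 of 17 genes higher, with Treml1 at 189-fold and Pf4 at 123-fold. Of 21 stem and progenitor genes, 12 were higher, among them Myb (at least 169-fold), Hmga2 (at least 82.2-fold), Lin28b (at least 39.6-fold), Cd34 (15.2-fold) and Kit (6.17-fold), and only Ly6a, which encodes the stem cell antigen Sca-1, was lower (8.05-fold). Neutrophil genes were higher for 10 of 21, led by Mpo (at least 701-fold) and Camp (at least 51.4-fold). Eosinophil, basophil and mast cell genes were higher for 2 of 9, Prg2 (at least 9.75-fold) and Gata2 (7.46-fold). Their list median became lower in fetal liver among genes well above background on all 3 arrays.

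Towards adult liver, the largest measured differences were those of Ces3b (9897-fold), Cyp3a41a (7187-fold), the gluconeogenic enzyme Fbp1 (5448-fold), Serpina3k (5020-fold), Mug1 (4901-fold), Cyp2a5 (4487-fold), and the major urinary proteins Mup1 (4424-fold) and Mup3 (3347-fold). The brightest genes not well above background in fetal liver were Cyp2f2 (at least 7078-fold), Mup10 (at least 6598-fold), Cidea (at least 4803-fold) and Mup5 (at least 4602-fold). All 22 genes of drug metabolism were higher in adult liver, with a median of 176-fold and Cyp2e1 at least 3600-fold apart. So were all 20 genes of the urea cycle and amino acid catabolism (median 104-fold), led by Cps1, the first urea cycle enzyme (at least 2744-fold), and Mat1a (998-fold). Bile acid genes were higher for 15 of 16 (median 85.1-fold, with the transporter Slco1b2 at 3151-fold), gluconeogenesis and glycogen genes for 10 of 11 (18.2-fold, G6pc at 680-fold), and fatty acid oxidation genes for 12 of 16 (9.19-fold). Cholesterol and fatty acid synthesis was divided, with 8 of 18 genes higher in adult liver, such as Scd1 (340-fold), and the sterol enzyme Sqle 4.28-fold higher in fetal liver. In total 2019 genes were higher in adult liver, 1604 of them measured in both tissues.

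Plasma proteins were higher in adult liver for 17 of 19 genes with a median of 13.03-fold, and Alb, the gene of serum albumin (probe on chromosome 5, 90901598 to 90901657, mm9), differed by 5.64-fold with signals of 293000 and 67900. The brightest signal of the adult liver array was 449000, so the fold of Alb may be compressed. Apoc3 stood out at 2375-fold. Coagulation genes were higher for 19 of 20 (10.48-fold), complement genes for 18 of 19 (21.7-fold, with Mbl2 at 1939-fold) and acute phase genes for 13 of 15 (27.1-fold, with Saa2 at least 1002-fold). Liver transcription factors were higher for 13 of 20 (4.30-fold), led by the bile acid receptor Nr1h4 (38.7-fold) and Cebpa (15.6-fold). The iron hormone gene Hamp was at least 907-fold higher in adult liver, and 6 of 13 iron genes were higher there. Antigen presentation genes were higher for 12 of 15, among them H2-K1 (20.6-fold) and B2m (16.6-fold). Circadian clock genes were higher for 5 of 12, led by Nr1d2 (14.2-fold) and Dbp (13.8-fold), and interferon-stimulated genes for 3 of 13, led by Irf7 (15.7-fold). Among macrophage genes, the Kupffer cell lectin Clec4f was 79.9-fold and Vsig4 at least 51.6-fold higher in adult liver, 6 of 18 in all, while Spic (5.01-fold) and Marco (4.16-fold) were higher in fetal liver.

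Several lists did not stand apart between the livers. Endothelial genes had a median of 1.41-fold towards adult liver, although the sinusoidal genes Clec4g (36.2-fold) and Fcgr2b (25.1-fold) were higher there and Lyve1 was 5.98-fold higher in fetal liver. Stellate and mesenchymal genes were divided, with Ptn (at least 28.1-fold) and Col1a1 (9.10-fold) higher in fetal liver. Lrat, which encodes an enzyme of retinol storage (at least 29.2-fold), and Dcn (4.92-fold) were higher in adult liver. Bile duct genes went both ways, with Spp1 157-fold higher in adult liver and Tspan8 at least 20.6-fold higher in fetal liver. The list of extracellular matrix and adhesion genes, called extracellular matrix for short below, included Itga4, 38.5-fold higher in fetal liver. It also included Col18a1, 11.9-fold higher in adult liver. Niche factors included Igf1, 85.4-fold higher in adult liver, beside Igf2 and Dlk1 in the opposite direction. Bone and stromal genes had Vcam1 5.37-fold higher in fetal liver and Cxcl12 5.21-fold higher in adult liver. T and NK cell genes included Zap70, at least 108-fold higher in adult liver, and Lck, 5.34-fold higher in fetal liver. B-lineage genes, whose median was 2.07-fold higher in adult liver and did stand apart, had 3 of 14 members higher there, led by Dntt (11.7-fold). Across lists, 9 stood apart towards fetal liver and 20 towards adult liver, out of 40. With normexp background correction, 1103 genes instead of 1707 were higher in fetal liver.

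**Figure D2:**
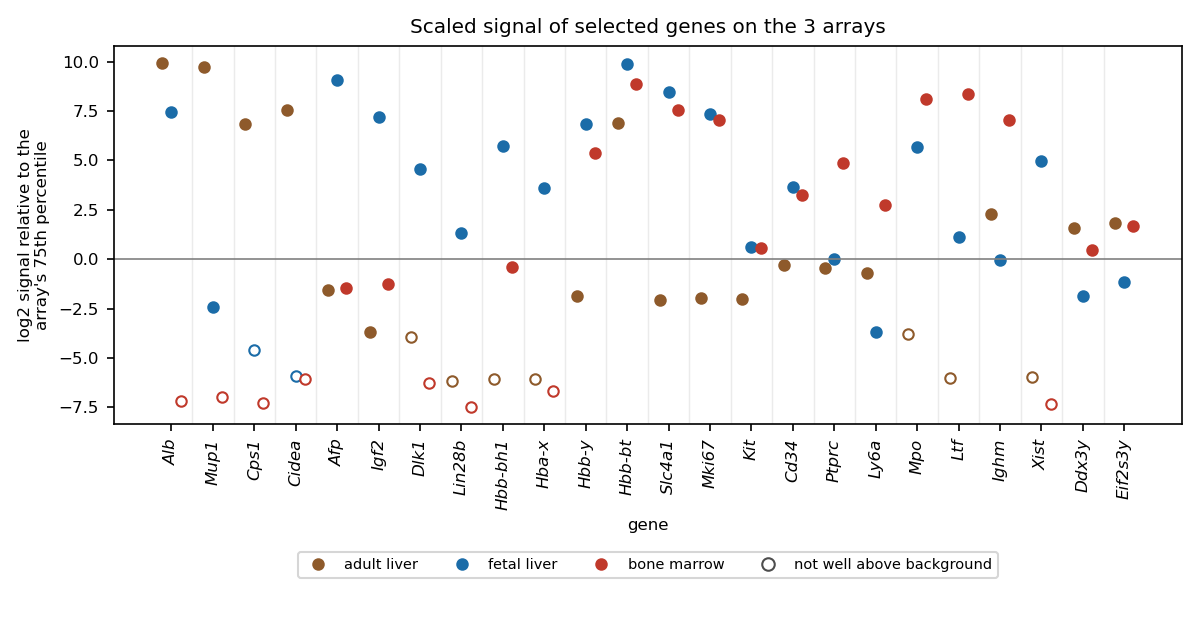
Scaled log2 signal (log2 of the processed signal minus the array's 75th percentile) of selected genes on the arrays of adult liver, fetal liver and bone marrow. Open circles mark signals not well above background. In this scaling Kit and Cd34 lie close together in fetal liver and bone marrow, differing by 1.03-fold and 1.29-fold, whereas Ptprc differs by 29.0-fold.

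Fetal liver and bone marrow were compared as 2 blood-forming organs. Red cell and cell division lists had medians within 4-fold, myeloid, lymphoid and antigen presentation genes were higher in bone marrow, and liver proteins and fetal growth genes were higher in fetal liver. None of 25 erythroid genes differed by 4-fold, with a median of 1.70-fold towards fetal liver that stood apart narrowly, at the 97.6th percentile, and the most different was Kel (2.67-fold). The adult beta globin gene Hbb-bt differed by 1.98-fold, but its signals of 361000 and 422000 lay near the brightest on their arrays (444000 and 483000), so this fold is uncertain. Of 28 cell cycle genes, only Cdk1 passed 4-fold (5.40-fold higher in bone marrow), and the median was 1.17-fold. Heme synthesis had Alas1 (7.72-fold higher in bone marrow) as its only member past 4-fold, and platelet genes had Selp (9.10-fold higher in bone marrow) as theirs, with a list median of 1.49-fold towards bone marrow that stood apart. With scaling to spike-ins, chosen after the data were seen, the medians on the log2 scale were -1.60 for erythroid and -2.14 for cell cycle genes, so the closeness of the tissues in these lists depends on the scaling.

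Stem and progenitor genes did not stand apart as a list (median 1.18-fold), and 16 of 24 were within 4-fold, with Kit at 1.03-fold, Cd34 at 1.29-fold and Myb at 1.07-fold. With spike-in scaling the log2 difference was -2.26 for the list median, and Kit passed 4-fold towards bone marrow, so that this closeness depends on the scaling too. Those higher in fetal liver included Hmga2 (156-fold), Lin28b (at least 95.4-fold), Sox17 (at least 20.6-fold) and Fgd5 (at least 20.5-fold). Of these, Lin28b and Hmga2 are known regulators of fetal blood formation, but both also belong to the oncofetal list. Which cells of the tissue gave these signals was not measured. Those higher in bone marrow were Ly6a (85.6-fold), the myeloid and B-cell factor Spi1 (at least 20.7-fold) and Erg (6.15-fold). Ptprc, which encodes the leukocyte antigen CD45 (probe on chromosome 1, 139960089 to 139960148, mm9), was 29.0-fold higher in bone marrow, with signals of 26190 and 390.9, and 3 of its 4 probes passed 4-fold.

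White cell lists were higher in bone marrow. All 22 neutrophil genes were higher there with a median of 109.5-fold, led by Chil3 (1916-fold), Lcn2 (657-fold), Retnlg (656-fold) and Mmp9 (426-fold). Eosinophil, basophil and mast cell genes were higher for 11 of 12 (median 21.5-fold), with the major basic protein gene Prg2 at 404-fold and Epx at 299-fold. The eosinophil ribonuclease family, whose members resemble one another on these probes, gave Ear6 at 1229-fold, Ear1 at 1103-fold and Ear10 at 978-fold. B-lineage genes were higher for 20 of 22 (40.1-fold), led by Pou2af1 (260-fold), Vpreb3 (247-fold) and Ms4a1 (232-fold), and among immunoglobulin genes Iglv1 reached 902-fold and Igha 738-fold. T and NK cell genes were higher for 11 of 18 (9.33-fold), led by Ccl5 (117-fold). Antigen presentation genes were higher for 14 of 15 (18.9-fold), led by H2-Aa (at least 131-fold) and H2-Ab1 (88.8-fold). Macrophage genes were higher for 7 of 18, such as Cd163 (at least 25.1-fold) and Cd68 (13.4-fold), while Clec4f (at least 6.14-fold), Timd4 (5.70-fold) and Marco (5.62-fold) were higher in fetal liver. Bone and stromal genes were higher in bone marrow for 7 of 15, led by Adipoq (at least 72.2-fold) and Ebf3 (36.2-fold), and interferon-stimulated genes for 5 of 14, led by Rsad2 (84.6-fold). The brightest genes not well above background in fetal liver were Chil4 (at least 1876-fold), Ear7 (at least 1243-fold), Ear3 (at least 799-fold) and the immunoglobulin joining chain Jchain (at least 635-fold). In total 1227 genes were higher in bone marrow.

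Towards fetal liver, plasma proteins were higher for 15 of 19 genes (median 210.5-fold), with Alb at least 6618-fold, Serpina6 at least 5351-fold, Rbp4 at 4925-fold, Ahsg at 2319-fold and Ambp at 2108-fold. Hp (52.1-fold) and Cp (7.70-fold) were instead higher in bone marrow. Serpina1d was 3144-fold, Serpinf2 999-fold and Apom 941-fold higher in fetal liver. Coagulation genes were higher for 15 of 20 (73.9-fold), with Fgg at least 1998-fold and Fgb at 1464-fold, while F5, also carried by platelets, was 5.91-fold higher in bone marrow. Liver transcription factors were higher for 14 of 20 (22.1-fold), among them Foxa2 (at least 160-fold) and Tbx3 (at least 140-fold). Complement was higher for 12 of 18 (9.91-fold, with Cfi at least 604-fold). Oncofetal and imprinted genes were higher for 17 of 20 (133-fold), with Afp at 1492-fold, Dlk1 at least 883-fold, Gpc3 at least 706-fold and Meg3 at least 611-fold. Among embryonic globins, Hba-x was at least 452-fold and Hbb-bh1 69.6-fold higher in fetal liver, whereas Hbb-y differed by only 2.82-fold. Of metabolic lists, the urea cycle and amino acid genes were higher for 10 of 17 (6.00-fold, with Agxt at least 128-fold). Stellate and mesenchymal genes were higher for 10 of 19 (4.44-fold), led by Lhx2 (at least 113-fold) and Ptn (at least 67.7-fold), while Acta2 was 6.68-fold higher in bone marrow, a difference that turned around with the mean of its probes. In total 1366 genes were higher in fetal liver, among them Igfbp1 (at least 1452-fold).

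Smaller shifts towards fetal liver concerned lists that turned towards bone marrow under spike-in scaling. These were cholesterol and fatty acid synthesis (7 of 18 genes, among them Lss at 12.3-fold), endothelial genes (9 of 20, led by Lyve1 at 27.6-fold), drug metabolism (6 of 16, led by Gsta3 at least 205-fold), bile acid genes (4 of 10, led by Abcb11 at 53.0-fold), fatty acid oxidation (5 of 16, led by Fabp1 at 893-fold), gluconeogenesis (3 of 9, led by Gys2 at least 544-fold) and extracellular matrix (9 of 26, led by Vtn at least 825-fold). Fbp1 was 14.8-fold, Spp1 198-fold and Fcgr2b 46.7-fold higher in bone marrow. Acute phase genes had 5 of 14 members higher in bone marrow and 2 higher in fetal liver, and their median turned towards fetal liver among genes well above background on all 3 arrays. Iron genes (median 1.37-fold, with Trf 5.99-fold higher in fetal liver), niche factors (1.38-fold, with Il1b at least 411-fold higher in bone marrow), clock genes (1.09-fold) and bile duct genes (2.06-fold, with Onecut1 at least 43.2-fold higher in fetal liver) did not stand apart. Across lists, 18 stood apart towards fetal liver and 12 towards bone marrow, out of 40. With normexp background correction 866 genes were higher in fetal liver, and with spike-in scaling 308 were higher in fetal liver and 7983 in bone marrow.

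Adult liver and bone marrow were the most different pair, with 2684 genes higher in adult liver and 2142 in bone marrow. The largest measured differences towards adult liver were those of Fabp1 (14610-fold), Fgb (13600-fold), Rbp4 (13290-fold), Serpina1d (13050-fold), Mup3 (12240-fold), Serpinc1 (10440-fold), Akr1c6 (9889-fold) and Ambp (9811-fold). Alb (at least 37340-fold), Mup1 (at least 31600-fold), Fgg (at least 21410-fold) and Ces3b (at least 20640-fold) were not well above background in bone marrow. All 22 drug metabolism genes (median 995-fold), 20 of 20 urea cycle and amino acid genes (902-fold), 18 of 19 plasma proteins (5595-fold), 19 of 20 coagulation genes (895-fold), 19 of 19 complement genes (253-fold), 10 of 11 gluconeogenesis and glycogen genes (368-fold), 15 of 16 bile acid genes (130.1-fold), 17 of 20 liver transcription factors (117.5-fold), 12 of 15 acute phase genes (24.1-fold), 13 of 16 fatty acid oxidation genes (11.6-fold) and 11 of 18 cholesterol and fatty acid synthesis genes (9.53-fold) were higher in adult liver. Endothelial genes were higher for 12 of 20 (5.52-fold), led by Clec4g (51.3-fold) and Kdr (17.7-fold), and stellate and mesenchymal genes for 9 of 18 (4.90-fold). Extracellular matrix and adhesion genes were higher for 9 of 25 (2.11-fold), with 7 others higher in bone marrow, such as Itga4 at 31.98-fold. Iron genes were higher for 6 of 13 (3.05-fold, with Hamp at least 1325-fold). The medians of these 4 lists turned towards bone marrow under spike-in scaling.

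Towards bone marrow, the largest measured differences were those of S100a8 (2054-fold), Chil3 (894-fold), Slc4a1 (800.3-fold), Ear1 (610.5-fold), Ifitm6 (609.6-fold), Ear10 (592-fold), Ctsg (564-fold) and Mki67 (509-fold). Ltf (at least 5185-fold), Camp (at least 4012-fold), Prg2 (at least 3942-fold) and Mpo (at least 3868-fold) were not well above background in adult liver. Neutrophil genes were higher for 22 of 22 (median 487-fold), erythroid genes for 23 of 25 (91.1-fold), cell cycle genes for 27 of 28 (62.6-fold), eosinophil, basophil and mast cell genes for 10 of 12 (40.0-fold), platelet genes for 15 of 17 (27.2-fold, with Ppbp at 276-fold), B-lineage genes for 19 of 21 (24.7-fold), stem and progenitor genes for 12 of 20 (7.12-fold, with Myb at least 157.5-fold), T and NK cell genes for 11 of 18 (6.33-fold), bone and stromal genes for 8 of 14 (5.40-fold), heme synthesis genes for 5 of 12 (3.39-fold) and antigen presentation genes for 5 of 15 (2.97-fold). Among the stem and progenitor genes, 2 were instead at least 4-fold higher in adult liver. Of the embryonic globins, Hbb-y was 150.3-fold and Hbb-bh1 at least 12.0-fold higher in bone marrow than in adult liver. Ptprc was 39.5-fold, Cd34 11.8-fold and Kit 6.01-fold higher in bone marrow. Macrophage genes did not stand apart (median 1.19-fold), with Clec4f at least 491-fold higher in adult liver and Cd68 7.64-fold higher in bone marrow. Niche factors (1.37-fold), interferon-stimulated genes (1.58-fold), bile duct genes (2.24-fold), clock genes (2.45-fold) and oncofetal genes (1.48-fold) did not stand apart either, although Igf2 was 5.34-fold higher in bone marrow than in adult liver. Across lists, 18 stood apart towards adult liver and 12 towards bone marrow, out of 39. With spike-in scaling, 831 genes were higher in adult liver and 9858 in bone marrow.

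Over the 3 tissues, 1626 genes were high in adult liver, 1091 low in adult liver, 788 high in bone marrow and 845 low in bone marrow, against 259 high and 236 low in fetal liver. Some genes, 584 in all, took 2 patterns at once, such as Alb, which was high in adult liver and low in bone marrow. The most distinct genes high in fetal liver were Afp, Bex2 (at least 563-fold over adult liver), Xist, Dlk1, Igf2, H19, Bex1 (at least 261-fold) and the keratin gene Krt20 (at least 234-fold). Those low in fetal liver were Lrg1 (904-fold below adult liver and 363-fold below bone marrow), Wfdc21 (373-fold and 187-fold), Ly6d (167-fold and 577-fold), Spp1 (157-fold and 198-fold), Xdh (201-fold and 84.7-fold), Hsd11b1 (382-fold and 80.1-fold), the retinoic acid enzyme gene Aldh1a1 (1069-fold and 74.9-fold) and AW112010 (407-fold and 65.7-fold). Shared by fetal liver and bone marrow and low in adult liver were Eraf, Rhd, Slc4a1, Hemgn, Mpo, the amino acid transporter Slc38a5, Rgcc and Mki67. With spike-in scaling the balance turned, to 713 genes high and 2452 low in adult liver and 6636 high and 195 low in bone marrow. Some alternatives set beforehand also turned the balance in bone marrow and fetal liver, but none did in adult liver. Median scaling gave 1018 high and 634 low in bone marrow, and 211 high and 308 low in fetal liver. Quantile scaling gave 859 and 725 in bone marrow, and 257 and 285 in fetal liver. Normexp and the authors' table turned both as well. The count high in fetal liver was 122 with normexp background correction and 424 without filter or bounds. Other pattern counts moved too. Normexp gave 131 low in fetal liver, 727 low in adult liver and 548 low in bone marrow. Restriction to genes well above background on all 3 arrays gave 1017 high in adult liver and 435 high in bone marrow.

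Sex chromosome genes differed between the samples. Xist, the RNA of the inactive X chromosome (probe on chromosome X, 100658920 to 100658979, mm9), had a signal of 12100 in fetal liver and was not well above background in adult liver or bone marrow, at least 490-fold and 1179-fold apart. The Y-linked genes Ddx3y (10.7-fold and 4.97-fold) and Eif2s3y (7.86-fold and 7.11-fold) were lower in fetal liver than in adult liver and bone marrow but well above background there, with signals of 108 and 173. Kdm5d and Uty were not well above background in fetal liver, with Kdm5d at least 5.75-fold and 6.78-fold and Uty at least 2.65-fold and 1.03-fold lower. Of the liver genes known to be biased by sex, 14 of 14 compared were higher in adult than in fetal liver, and 14 of 14 were higher than in bone marrow. Between fetal liver and bone marrow, 3 of 10 were higher in fetal liver, with a median that turned under spike-in scaling, as did the direction of Cyp2d9 (4.70-fold).

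Markers of tissues that could be carried along in dissection were also compared. Skeletal muscle genes were higher in bone marrow than in adult liver for 4 of 8 compared, led by the fast myosin gene Myh4 (at least 18.04-fold) and Mylpf (15.5-fold), and 1 of 11 was higher in bone marrow than in fetal liver, while Mylpf was 11.5-fold higher in fetal than in adult liver. Adipocyte genes were higher in adult liver for 3 of 5 compared with bone marrow and 3 of 4 compared with fetal liver, led by Car3 (2451-fold over bone marrow) and Cidec (1488-fold over bone marrow), and 2 of 5 were higher in bone marrow than in fetal liver. Exocrine pancreas genes had a median of 1.17-fold between fetal and adult liver, with Pnliprp1 at least 32.7-fold higher in fetal liver, 1.17-fold between fetal liver and bone marrow and 1.21-fold between adult liver and bone marrow. Gut epithelium genes had Fabp2 1539-fold higher in adult liver than in bone marrow and 30.1-fold higher than in fetal liver. Of the gut list, 3 of 4 members were higher in adult liver than in bone marrow, 2 of 5 higher in adult than in fetal liver, and 3 of 5 higher in fetal liver than in bone marrow. Of the kidney genes, 3 or 4 of 10 could be compared in any pair, with Wt1 4.57-fold higher in fetal than in adult liver. Between adult liver and bone marrow, 3 of 4 kidney genes were higher in adult liver and 1 in bone marrow (median 4.43-fold). Neither the kidney nor the pancreas list stood apart in any pair, but the others did. Skeletal muscle genes stood apart towards bone marrow, against adult liver (percentile 0.67) and fetal liver (1.99). Adipocyte genes stood apart towards adult liver, against fetal liver (0.0) and bone marrow (99.82). Gut genes stood apart against bone marrow, towards fetal liver (99.98) and adult liver (98.35).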

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

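With 1 array per tissue, every alternative below changes the handling of the same 3 arrays and none measures variation between animals. Spike-in scaling was the only alternative chosen after seeing the data. Leaving out saturated genes changed nothing, since there were none. Quantile scaling and the 75th percentile of probes well above background on all arrays kept each count within 1.5 times and each correlation within 0.05, and median scaling kept each count within 1.5 times. Relative to the main scaling, in which genes well above background on all arrays had medians of 0.02 (fetal minus adult liver), 0.27 (fetal liver minus bone marrow) and 0.14 (adult liver minus bone marrow) on the log2 scale, median scaling gave -0.03, -0.14 and -0.22, quantile scaling 0.08, 0.16 and -0.001, and spike-in scaling 0.56, -2.09 and -2.76. The share of calls towards fetal liver against bone marrow was 52.7% in the main scaling and 38.7% with median scaling, and that towards adult liver against bone marrow was 55.6% and 45.6%. With spike-in scaling these shares were 3.7% and 7.8%, and for fetal against adult liver 64.1% in place of 45.8%. Gene signals of the bone marrow array were brighter and its spike-ins dimmer, by 2.22-fold against fetal liver and 2.47-fold against adult liver. The labels used here do not state the amounts added, and the cause was not tested.

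Spike-in scaling gave 2636 genes higher in fetal than in adult liver, 308 higher in fetal liver and 7983 in bone marrow, and 831 higher in adult liver and 9858 in bone marrow. By pattern it gave 713 high and 2452 low in adult liver, 88 high and 585 low in fetal liver, and 6636 high and 195 low in bone marrow. Under it, among lists whose median had stood apart, the medians of 9 turned from fetal liver towards bone marrow, to -1.11 for drug metabolism (cytochrome P450), -1.07 for gluconeogenesis, -1.11 for bile acids, -1.45 for fatty acid oxidation, -0.69 for cholesterol and fatty acid synthesis, -1.60 for erythroid genes, -0.76 for endothelial genes, -1.48 for extracellular matrix and -0.80 for liver genes biased by sex. Between adult liver and bone marrow, 4 that had stood apart turned, to -1.29 for iron, -0.43 for endothelial, -0.93 for stellate and -1.87 for matrix genes. Cyp2d9 turned to -0.13 between fetal liver and bone marrow, and between adult liver and bone marrow AW112010 to -0.27, Alpl to -0.51, Cd5l to -0.54, Hsd11b1 to -0.64, Ifit3 to -0.36, Nr1d2 to -0.039 and Timd4 to -0.10. Lists that had not stood apart are left out of these counts, and some of them changed sign as well, such as cell cycle genes between fetal liver and bone marrow, to -2.14. All of these came from shifting whole arrays. Bounds that changed sign were left out and others entered, so the members behind some list medians changed as well.

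Normexp background correction, which also replaced the processed signal by the mean spot and local background intensity, gave 1103 genes higher in fetal than in adult liver, 866 higher in fetal liver than in bone marrow, 727 low in adult liver, 122 high and 131 low in fetal liver, and 548 low in bone marrow. The authors' table gave 171 genes high in fetal liver. Restriction to genes well above background on all arrays, which removes every bound, gave 796 genes higher in fetal liver than in bone marrow and 750 lower, 1423 higher in bone marrow than in adult liver, 1017 high in adult liver, 123 high in fetal liver, and 435 high and 528 low in bone marrow. It also turned the median of eosinophil, basophil and mast cell genes between the livers to -0.34 and that of acute phase genes between fetal liver and bone marrow to 0.12. Without filter or bounds, 424 genes were high in fetal liver and the correlations were 0.832, 0.892 and 0.746 (fetal with adult liver, fetal liver with bone marrow, adult liver with bone marrow). With the mean of all probes, adult liver and bone marrow correlated at 0.683, and Acta2 turned to 0.69 between fetal liver and bone marrow. The cause was not tested for any of the results in this paragraph.

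A 2-fold threshold, which admits smaller differences, gave 3808 and 3822 genes (higher in fetal and in adult liver), 3664 and 2510 (fetal liver, bone marrow), and 4654 and 3909 (adult liver, bone marrow). By pattern it gave 3048 high and 2414 low in adult liver, 1206 and 761 in fetal liver, and 1637 and 2014 in bone marrow. At 8-fold the numbers were 846 and 1175, 676 and 671, and 1636 and 1259, and by pattern 960 and 563, 89 and 88, and 434 and 429. No list medians were taken at these thresholds. Of 1176 list medians under the other alternatives, 595 moved by less than 0.19 on the log2 scale, 566 moved further with the sign kept or without having stood apart, and 15 turned. The limit of 0.19 is the spot noise of a difference for probes well above background. Of the 595, 119 came from leaving out saturated genes, which could change nothing. Another 118 came from the 75th percentile of probes well above background on all arrays, a scaling close to the main one.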

Other observations

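The tests of explanations below were all chosen after the values were seen. Several genes of lipid droplets and lipid synthesis were bright in adult liver, although no list was set for lipid droplets and only 8 of 18 genes of cholesterol and fatty acid synthesis were higher there than in fetal liver. Cidea, a lipid droplet protein gene best known from brown fat (probe on chromosome 18, 67527351 to 67527410, mm9), had a signal of 55100 in adult liver and was not well above background elsewhere. Cidec had 13600 in adult liver, 20.1 in fetal liver and 27.6 in bone marrow. Singled out after their values were seen, Plin4 was 105-fold higher in adult than in fetal liver, Mogat1 31.1-fold, Plin2 5.20-fold, Pparg 7.99-fold and the lipogenic regulator Thrsp at least 3417-fold.

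Adipose tissue carried along with the liver is a technical explanation for Cidea and Cidec. The adipocyte hormone gene Adipoq argues against it, since it was not well above background in adult liver and at least 43.8-fold higher in bone marrow. Of Adipoq, Plin1, Lep and Retn, 4 of 4 were not well above background in adult liver. Of the 9 adipocyte genes listed, Car3, Cfd, Cidec and Fabp4 were measured there. Other members of the list thus go the other way from Adipoq. Of 4 compared with fetal liver, 3 were higher in adult liver, with a list median of 227-fold that stood apart (percentile 0.0). Against bone marrow the list also stood apart towards adult liver (percentile 99.82). Both medians include Cidec itself and leave out members dim in both tissues. They therefore cannot decide whether adipose tissue was carried along. Lipid-loaded hepatocytes may be the source of Cidea and Cidec, as a hypothesis that these arrays hold no test for.

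The embryonic globin gene Hbb-y (probe on chromosome 7, 111001412 to 111001471, mm9) had a signal of 37000 in bone marrow and 45200 in fetal liver, 2.82-fold apart after scaling. Fetal RNA in the bone marrow sample would bring other fetal transcripts to a similar level, but Afp, H19, Igf2, Dlk1, Hbb-bh1 and Hba-x were lower in bone marrow by a median of 487-fold. Adult beta globin RNA binding the Hbb-y probe remains open. From adult liver to bone marrow Hbb-y was 150.3-fold and adult beta globin (Hbb-bt) 3.94-fold higher, a ratio of 38.2, yet at 422000 the latter may be compressed near the top of the scanner range, so that the 2 sources cannot be told apart. Expression of Hbb-y in marrow red cells is the biological alternative, and was not tested.

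The fetal liver array showed Xist together with weak Y-linked signals. RNA of male fetuses only is argued against by Xist, at least 490-fold above the arrays of adult liver and bone marrow alike. Adult male liver RNA in the sample is argued against by Mup1, whose deficit in fetal liver was 413.5 times that of Ddx3y. Fetuses of both sexes in 1 sample could give this picture, as 2 of 4 Y-linked genes were well above background. Signal from the X-linked copies of these genes on the same probes cannot be told apart from it, because those copies were not measured separately. In either case sex differs between the fetal liver sample and the other samples beside age and tissue.

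Although Xist was not well above background in adult liver, signals of genes known as female-biased were mixed there. Cyp3a41a (105000), Cyp3a44 (19700), Cyp2a4 (6090) and Cyp2b9 (2780) were well above background, whereas A1bg, Sult2a2 and Sult3a1 were not. The male-biased Mup1 (248000), Cyp4a12a (19100) and Hsd3b5 (7370) were well above background. The Cyp3a and Cyp2a genes belong to families of close relatives.

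Among unnamed probes, 246 were at least 4-fold higher in fetal than in adult liver and 298 lower, out of 3025 compared. Against bone marrow, 636 were higher in fetal liver and 230 lower, out of 3276, and 760 were higher in adult liver and 340 lower, out of 2906.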
